A study of Mus musculus with 8 samples.

How the data were processed

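Skin of mouse pups aged 7 days was compared between near naked hairless mutants and wild type mice by 2-colour hybridization to spotted oligonucleotide arrays. The series held 8 arrays. Channel 1 carried the RNA called sample and channel 2 the RNA called control in the labels. The design text names the mutant first, so that sample was read as mutant and control as wild type. The mutant RNA was labelled with Cy3 on arrays 1, 3, 5 and 8 and with Cy5 on arrays 2, 4, 6 and 7. The design text states 5 biological replicates from 1 litter, and the labels do not tie arrays to animals. With 8 arrays and 5 replicates some arrays shared RNA of an animal, so p-values over arrays are too small and measure in part the technical spread.

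The authors deposited log ratios of the 2 channels, taken here as log2 values. A base of 10 would exceed the range of a scanner. A natural logarithm was not excluded, so the sizes below rest on the assumed base of 2. The base, the direction of the ratio, the image analysis, the normalization and the rule for missing values are not given in the sources used here. Labelling and hybridization followed standard protocols, per the labels. The table had 23232 rows, and an array had values for between 9585 and 20519 of them. The values of the 8 columns had medians of 0.02, 0.05, 0.01, 0.13, -0.01, 0.02, 0.08 and -0.13 for arrays 1 to 8, so that they were already centred. Their spread was not equalised, with an SD from 0.57 on array 5 to 1.60 on array 2. Spot intensities were not analysed here, so no signal over background stood behind a value, and the number of arrays set the precision.

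Control spots were left out of the tests. They were 864 blank spots, 275 spots of buffer and 96 spots of a control oligonucleotide without a mouse target. The 232 replicate spots of Gapdh were averaged into 1 probe. Rows were named through a table of mouse genes of the assembly GRCm38.p6, used for names and for the order of genes alone, by accession without version. Of 21997 rows with a probe, 6749 matched a gene by RefSeq accession, 77 matched by a synonym and 15171 had no match. Genes with several probes, 8 in all, took the mean of their probes, and none had called probes of opposite sign.

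The direction of the ratios was examined before any fit. The rule set for this, before the data were examined, compared correlations between arrays of the same and of opposite dye orientation. It gave no verdict, because the 16 pairs of opposite orientation split into 6 positive and 10 negative correlations over probes (median r = -0.02), while all 12 pairs of the same orientation were positive (median r = 0.49). The split rested in part on array 8, since 3 of its 4 pairs of opposite orientation were positive (median r = 0.17), against 3 of the other 12 (median r = -0.14). The Alien control spots correlated below 0 in 13 of the 16 pairs, and in all 12 without array 8. A check chosen after seeing the data used the replicate Gapdh spots, which carry the same gene and cannot differ from spot to spot by genotype. Their differences correlated below 0 in all 16 pairs of opposite orientation (median r = -0.45, range -0.78 to -0.07) and above 0 in all 12 pairs of the same orientation (median r = 0.55). In a table of one dye over the other, a dye difference between spots would keep its sign on every array. The table was therefore read as already turned to a single direction, with the part common to all arrays as the genotype part and the part that follows the orientation as the dye part. The opposite reading was run as an alternative, as Cy5 over Cy3. Read as Cy3 over Cy5, every direction under it would turn, so those directions rest on this choice. The overall sign, mutant over wild type, is likely, from the order of the channels and of the design text, and is not stated in the sources used here. With the opposite sign every direction below would turn, while sizes, counts and tests would hold.

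Each probe or gene with values on at least 3 of the 4 arrays of each orientation was fitted with a mean ratio and a dye term in limma 3.58.1 under R 4.3.3, with empirical Bayes moderation and Benjamini-Hochberg adjustment at a threshold of 0.05. The filter left 11974 probes and 3779 genes. The lists of genes, 22 in all, were fixed before the data were examined. They were tested with camera on the moderated statistics, two-sided, with a preset correlation of 0.01, adjusted over the lists. Camera was run on moderated statistics converted to z scores, since its usual form takes no missing values. A correlation was also estimated where at least 3 members had values on all arrays, with negative estimates set to 0, and fry was run on genes with values on all arrays. The median of a list over its members with a value, whether or not they passed the filter, was tested across arrays with an exact sign-flip test.

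Genes were named by a rule fixed before the data were examined. It took the 12 highest and the 12 lowest fitted ratios among genes past the threshold with the same sign on every array that measured them, the gene Hr, and up to 4 members of each list with the smallest p. Genes singled out in other ways are marked as chosen after their values were seen.

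The fits were tested on simulated data with 200 changed rows. At the probe level, where 11974 rows were run, 1.49% of changes of 0.5, 46.3% of changes of 1 and 100% of changes of 2 on the log2 scale were recovered, and 4.85% of calls were false. At the gene level, with 3779 rows, the shares were 10.4%, 64.2% and 98.5%, with 1.71% false calls. The simulated noise was normal and independent between rows and between arrays. These shares therefore do not give the error rate of the real calls, where some arrays shared RNA of an animal. Alternatives included no dye term, centring, scaling and quantile normalization between arrays, stricter and looser filters, averaging or blocking consecutive arrays, a robust prior, array weights, a minimum fold of 1.2 and leaving out each array. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 served for tables, exact tests and plots.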

Results

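Gene expression in whole skin of 7 day old near naked hairless mice, a mutant of the hairless locus with sparse hair, was set against that of wild type mice on 8 arrays with swapped dyes. The mutant RNA carried Cy5 on 4 arrays and Cy3 on the other 4. Between 41.3% and 88.3% of the rows of an array had a value, with the lowest shares on arrays 3, 2 and 1 (41.3%, 50.7% and 59.0%). Ratios are given as log2 of mutant over wild type, a direction that is likely and not stated in the sources used here. The arrays are the n of every test, although the design text states 5 biological replicates, so that p-values are smaller than biological replicates would give.

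**Figure D1:**
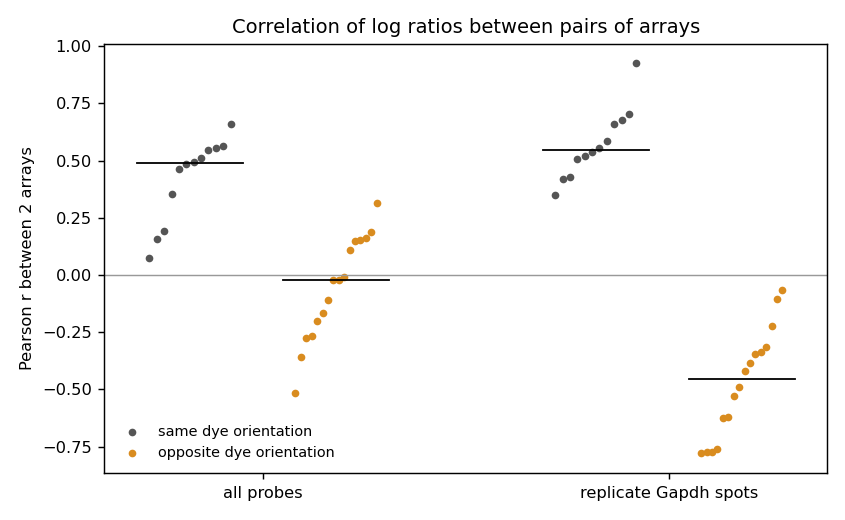
Pearson correlation of log ratios (vertical axis, no unit) between pairs of arrays, over all probes and over the replicate Gapdh spots. Each point is a pair of arrays and each line a median. Pairs of the same dye orientation had medians of 0.49 and 0.55, and pairs of opposite orientation had medians of -0.02 and -0.45.

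The question of the study was which genes differ in the skin of the mutant. The hairless gene itself, Hr, encodes a corepressor of nuclear receptors that is active in the hair follicle. Its single probe had a value on 6 arrays, 4 with the mutant in Cy5 and 2 with the mutant in Cy3. The mean log2 ratio was -0.17 ± 0.64 (SD, n = 6), with 3 arrays above 0 and 3 below (exact sign-flip test, two-sided, p = 0.594). A looser filter on missing values, chosen for Hr after seeing the data, gave -0.11 with a 95% interval from -0.75 to 0.52. A change of Hr RNA within that interval was not excluded. Whether the probe covers the part of Hr that is altered in the mutant is not known here, so it does not check the labels.

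Across named genes, the mutant skin had more lower than higher values among those past the test. Of 3779 genes, 25 were higher and 106 were lower in the mutant (limma, adjusted p below 0.05). Among the genes that rose were Cfd, the complement factor D made by adipocytes, Krt1, a keratin of the suprabasal epidermis, Gli3, a transcription factor of the Hedgehog pathway, and Vim, the intermediate filament protein of mesenchymal cells. Among those that fell were Has1, which makes hyaluronan, Grpr, the receptor of gastrin-releasing peptide, the epidermal fatty acid binding protein Fabp5, and the gap junction protein Gjb2. At the probe level 81 of 11974 probes were higher and 423 were lower, and 355 of these 504 had no gene name.

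Among genes past the threshold with the same sign on every array that measured them, the highest ratio was that of Cfd, at 1.96 ± 0.33 (SE, 7 arrays, adjusted p = 0.0102). Gli3 stood at 1.27 ± 0.19, Vim at 1.17 ± 0.19 and the mast cell protease gene Mcpt2 at 1.05 ± 0.18, each above 0 on 8 of 8 arrays. Krt1 reached 1.30, the secreted Wnt antagonist Sfrp1 1.2, Igfbp7 1.14 and the proteoglycan gene Aspn 1.01, each above 0 on 7 of 7 arrays. Pramel3 at 1.27, Surf6 at 1.04 and Pa2g4 at 1.01 completed the group with Npdc1. Npdc1 had a mean of 1.65, with values from 2.20 to 3.42 on arrays 1 to 4 and from 0.26 to 0.52 on arrays 5 to 8.

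Under the same limit, the lowest ratios were those of Has1 at -2.28 ± 0.48 (SE, 7 arrays), Grpr at -2.14 ± 0.23 and Angptl1 at -2.05 ± 0.29. The homeobox gene Vax1 stood at -2.02, Ilf2 at -1.78, Sh3bp5l at -1.76, the cohesin subunit gene Stag1 and the membrane fusion gene Stx4a both at -1.69. Fabp5 followed at -1.59, Sec61a2 at -1.58, and Ndufa2, a subunit of respiratory complex I, and Gjb2 at -1.54. All 12 were below 0 on every array that measured them. Has1 was at -6.18 on array 2 and no lower than -2.75 elsewhere, and Vax1 at -5.56 on array 2 and no lower than -2.36 elsewhere.

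**Figure D2:**
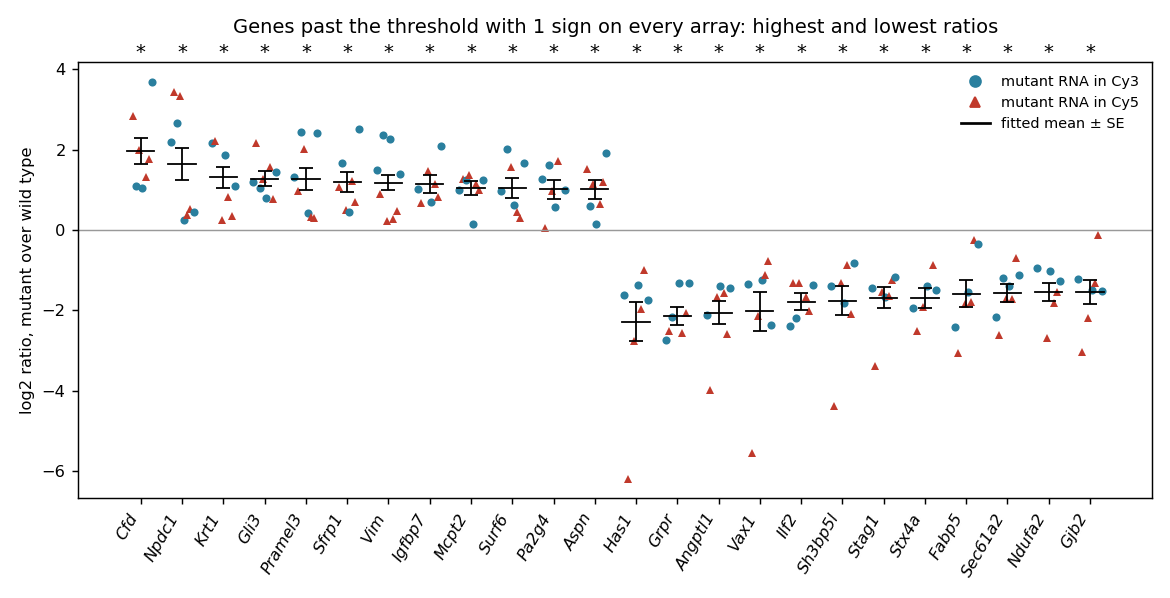
Log2 ratio of mutant over wild type (vertical axis) on each array for the 12 genes with the highest and the 12 with the lowest fitted ratios among those past the threshold with the same sign on every array. Points are arrays, by the dye of the mutant RNA, and black lines are fitted means with the SE. Fitted means ran from 1.96 for Cfd to -2.28 for Has1.

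Of these 24 genes, 11 stayed past the threshold whichever array was left out: Cfd, Gli3, Vim, Mcpt2, Grpr, Angptl1, Ilf2, Stag1, Stx4a, Sec61a2 and Ndufa2. Of the 11, only Gli3, Vim, Mcpt2 and Sec61a2 had values on all 8 arrays. For the rest of the 11, at least 1 of these fits left out an array without a value for the gene. The fitted ratio was then unchanged, as for Angptl1 without array 3. The other 13 of the 24 lost the call without at least 1 array, with adjusted p up to 0.170. Surf6 and Aspn kept it in 0 of 8 such fits, and Pa2g4 in 1 of 8. Without arrays 1 to 8 in turn, 12, 6, 6, 11, 10, 11, 7 and 6 of the 24 were lost. The count of genes fell from 131 to 53 without array 1, 85 without array 2, 82 without array 4, 72 without array 5 and 60 without array 6. Of the 11 members of the gene lists that passed outside these 24, 1, Krtap9-1, kept its call in every such fit. With quantile normalization the split was 135 higher and 225 lower genes, against 25 and 106, and 380 higher and 757 lower probes, against 81 and 423. With arrays 4 to 8 alone, an alternative chosen after seeing the data because arrays 1 to 3 had the fewest values, 8 genes were past the threshold, all lower, and 103 probes.

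The keratin-associated proteins, which form the matrix between the keratin filaments of the hair shaft, fell as a list in the mutant (camera, adjusted p = 1.2e-05, and adjusted p = 0.000181 with an estimated correlation). That correlation was estimated on only 3 members, those with values on all arrays. Of 8 members tested, all 8 had fitted ratios below 0, 3 were lower past the threshold, none was higher and 5 did not pass. Adjusted over the list alone, 6 were lower. Krtap15 stood at -1.33 ± 0.28, Krtap14 at -1.28 ± 0.30 and Krtap9-1 at -1.26 ± 0.22, the last below 0 on 8 of 8 arrays. Krtap1-5 had a ratio of -1.46 with an adjusted p of 0.0972. The median over all members with a value on an array, tested or not, was below 0 on 8 of 8 arrays. It ran from -2.22 on array 3 to -0.08 on array 7, with a mean of -1.15 ± 0.75 (SD, n = 8). An exact sign-flip test gave p = 0.00781, the smallest that 8 arrays can give, and 0.115 adjusted over 22 lists. Krtap5-2, chosen after its values were seen, was above 0 on 4 arrays and below 0 on 4, with a dye part of 1.15 (adjusted p = 0.0286).

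The hair keratins had 3 members tested. Krt31, a keratin of the hair cortex, fell by 1.27 (SE 0.23, below 0 on 7 of 7 arrays), while Krt33a at -0.58 and Krt35 at 0.63 did not pass, and Krt35 was at 4.83 on array 8. Over the list alone 2 were lower. The list did not pass (adjusted p = 0.261). Of 7 genes of the inner root sheath and medulla, the sheath that encloses the growing hair, Krt71 fell by 0.79 (SE 0.18, below 0 on 8 of 8 arrays), and 6 did not pass, among them Krt27 at -0.77, Tgm3 at -0.36 and Padi3 at -0.28, which ran from -0.69 to -0.01 and from -0.44 to -0.16 without 1 array. Over the list alone 2 were lower, and the list had an adjusted p of 0.136. Fry, which tests whether members move one way without comparing them with other genes, called the list lower on 5 members with values on all arrays (adjusted p = 0.0145). Beside Krt71 and Krt27 these were Trps1 at -0.05, S100a3 at -0.02 and Gata3 at 0.12, so that call rested mainly on Krt71 and Krt27. Of the 7 tested members 6 had fitted ratios below 0. The median over members with a value was below 0 on 7 of 8 arrays (exact sign-flip test, adjusted p = 0.270). A fall across the list was therefore neither established nor excluded. Krt27 itself had a mean of -1.53 with the mutant in Cy5 and of -0.01 with the mutant in Cy3. Among 21 regulators of the hair matrix, 1 was lower, Fgf5, a signal that ends the growth phase of hair, at -1.11 ± 0.20. Fgf7 at 0.63, Foxn1 at 0.47 and Bmpr1a at -0.97 did not pass (list adjusted p = 0.804). Left out in turn, arrays ended the call of Krt31 (array 5), Fgf5 (arrays 1 and 6), and of Krtap14, Krtap15 and Krt71 in most fits, whereas Krtap9-1 stayed past the threshold in all 8 fits. The keratin-associated list also stayed past it in all 8.

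**Figure D3:**
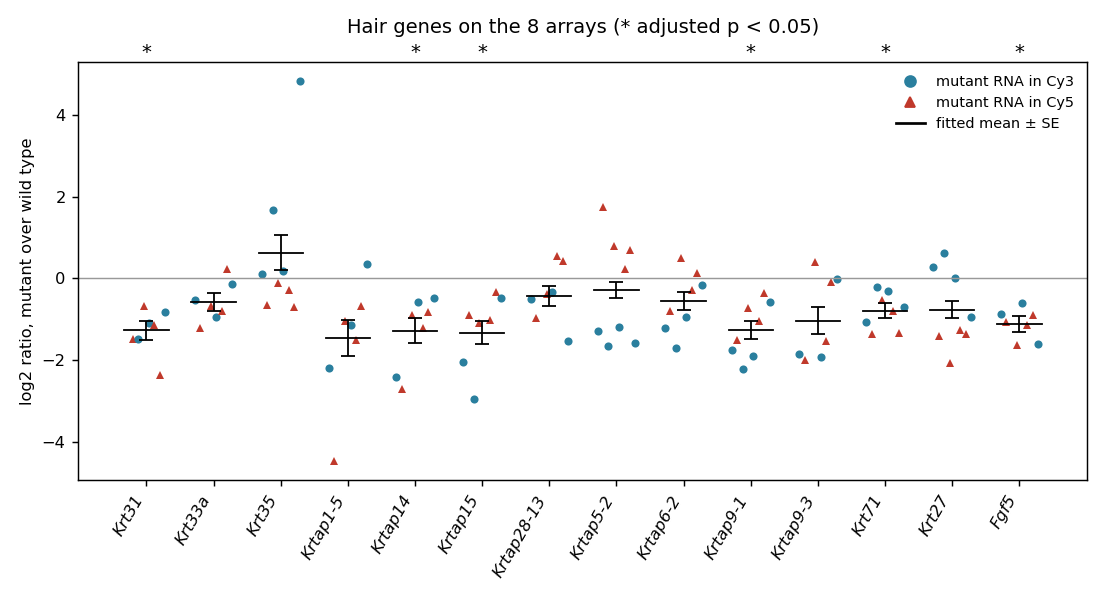
Log2 ratio of mutant over wild type (vertical axis) on each array for hair keratins, all tested keratin-associated protein genes, 2 inner root sheath keratins and Fgf5. Points are arrays, by the dye of the mutant RNA, black lines are fitted means with the SE, and stars mark adjusted p below 0.05. The fitted means of the 8 keratin-associated protein genes all lay below 0.

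The list of dermal fibroblast and extracellular matrix genes was higher with the preset correlation (adjusted p = 0.0261), with 19 of 26 members above 0. With an estimated correlation the list was not past the test (adjusted p = 0.679). Vim at 1.17 and the fibrillin gene Fbn1 at 0.75 were higher, the latter with 6 arrays above 0 and 2 below, and 24 members did not pass, among them Postn at 0.75 and Sparc at 0.93. Adjusted over the list alone 4 were higher and 1 was lower. The call was lost without array 6 (adjusted p = 0.116) and without array 8 (0.134). In the dermal papilla, the mesenchymal core of the follicle, 9 members were tested and none passed, with Vcan at 0.81 and Cntn1 at 0.46 (list adjusted p = 0.411). Over that list alone 2 were higher.

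The cytosolic ribosomal protein genes were higher as a list with the preset correlation (adjusted p = 0.0261), with 36 of 43 members above 0. With an estimated correlation they were not past the test (adjusted p = 0.679). No member was higher past the threshold, and Rpsa, a ribosomal protein also known as a laminin receptor, was lower at -0.78 ± 0.17, below 0 on 8 of 8 arrays. Rpl13a at 0.68 and Rpl36a at -0.76 did not pass. The call was lost without array 4 (adjusted p = 0.212), array 5 (0.138) and array 8 (0.134). Of 29 genes of oxidative phosphorylation 1 was lower, Ndufa2, and Atp5a1 at 0.71 and Atp5b at 0.62 did not pass (list adjusted p = 0.842).

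Epidermal genes went both ways. Of 23 genes of epidermal differentiation and the cornified envelope 2 were higher, Krt1 at 1.30 and Lce1e at 1.05, and adjusted over the list alone 6 were higher and 5 lower (list adjusted p = 0.487). Fry called this list higher on 12 members with values on all arrays (adjusted p = 0.0243). Lce1e was above 0 on 5 arrays and below on 3, with a dye part of 1.12 (adjusted p = 0.0286). Sprr1b at -1.04 and Lce1f at 0.81 did not pass. Of 12 genes of stressed and activated keratinocytes, 2 were lower, Gjb2 and Fabp5 (list adjusted p = 0.487). Serpinb3a at 0.70 had an adjusted p of 0.0511 with 8 of 8 arrays above 0. Adjusted over that list alone 2 were higher and 3 lower. No member passed among 4 genes of basal keratinocytes (list adjusted p = 0.936) and 5 of desmosomes (0.933), where Col7a1 stood at 0.64 and Pkp3 at -0.28. Of 10 genes of proliferation none passed either, with Mcm2 at 0.82 and Rrm1 at 0.61 (list adjusted p = 0.321), and fry called the list higher on 5 members (adjusted p = 0.0396).

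Among known partners and targets of the hairless protein, 13 genes were tested and none passed (list adjusted p = 0.627). Rora, a nuclear receptor, stood at 0.94 (adjusted p = 0.0753) and the vitamin D receptor gene Vdr at -0.97 (adjusted p = 0.256), with Vdr at -4.80 on array 2. Of 5 genes of polyamine metabolism none passed, with Sms at 0.30 and Azin1 at 0.20 (list adjusted p = 0.765).

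Markers of other cell types of whole skin were read in the same way. In the adipocyte list Cfd was the 1 gene of 14 that rose, and Car3 stood at -0.86 and Lep at 0.43 (list adjusted p = 0.936). Fabp5 was the 1 gene of 14 lower past the threshold among sebaceous and epidermal lipid genes (list adjusted p = 0.321), where Scd3 stood at -0.78 and Cyp51 at 0.74. Of these 14, 9 had fitted ratios below 0 and 5 above. Of 20 immune cell genes, C1qb, a complement component of macrophages, fell by 1.37 (SE 0.25, below 0 on 7 of 7 arrays), and Lyz2 at -0.74 and Tyrobp at 0.71 did not pass (list adjusted p = 0.804). Mbp, the myelin basic protein gene, fell by 0.90 (SE 0.20) among 5 nerve genes (list adjusted p = 0.321). None of 9 melanocyte genes (0.487), 11 skeletal muscle genes (0.765) and 8 genes of blood and vessels (0.936) passed, with Trpm1 at -0.41, Tnnt3 at -1.23 and Pecam1 at -0.72. Of the 22 lists, 3 passed with the preset correlation. A correlation could be estimated for 16 lists, and 1 of these, that of the keratin-associated proteins, passed with it. Its estimate rested on 3 members. The hair keratins were among the lists without an estimate.

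**Figure D4:**
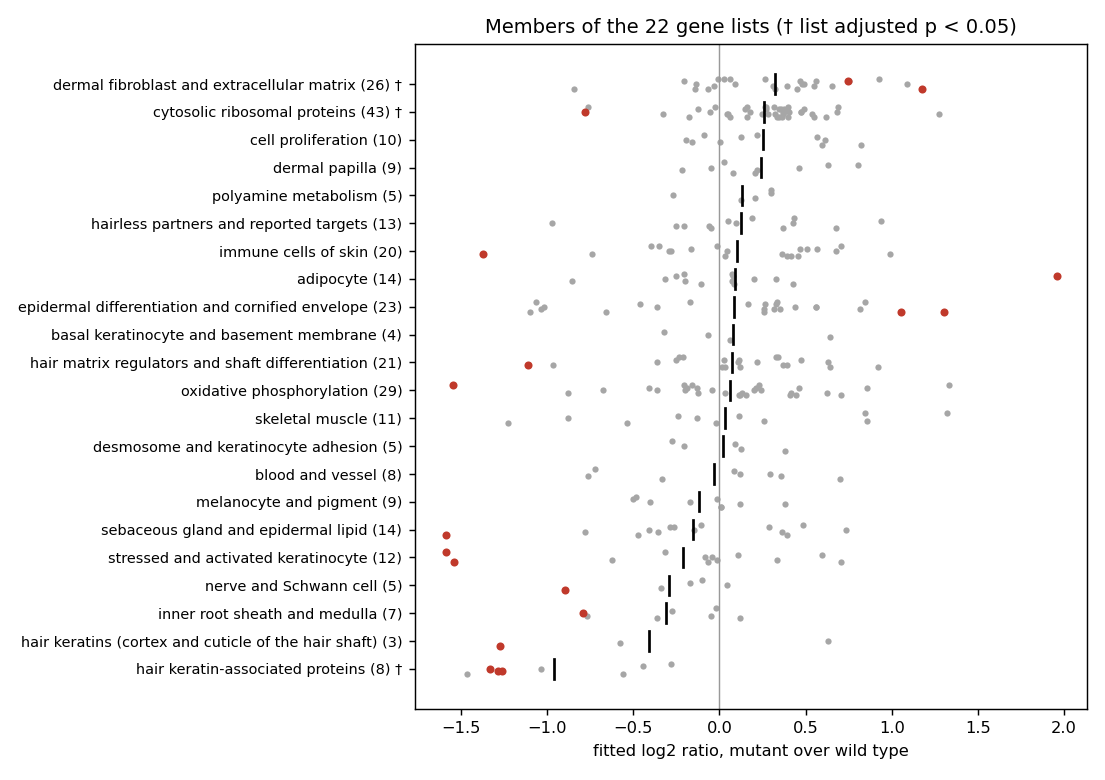
Fitted log2 ratio of mutant over wild type (horizontal axis) of each tested member of the 22 gene lists, with the number tested in parentheses. Red points are genes with an adjusted p below 0.05, black bars are list means, and daggers mark the 3 lists with an adjusted p below 0.05. The mean ran from -0.96 for the keratin-associated proteins to 0.32 for the dermal list.

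The dye effect, read as the part of the ratio that follows the orientation, was past the test for 62 genes with higher and 4 with lower ratios when the mutant RNA carried Cy5, and for 533 and 107 probes. Gapdh, a gene of glycolysis with 232 spots, had a fitted ratio of 0.17 ± 0.17 and a dye part of 0.13 ± 0.17, neither past the test. Centring each array on its median changed the count of probes with a dye effect from 640 to 407.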

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

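The tests of the dye orientation, of the Gapdh spots, of the correlation between family members and of arrays 4 to 8 alone were chosen after the results they bear on were seen. Of 133 sets of values over arrays that were examined, 19 had an array far from the others by Dixon's test, where chance gives about 1 in 20, or 6.65. Array 2 was that array in 11 sets and array 8 in 5. Array 2 had the widest spread of all (SD 1.60) and array 8 the highest single value (9.57).

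Values on array 2 lay far below the others for Has1 (-6.18), Vax1 (-5.56), Vdr (-4.80), Sh3bp5l (-4.38), Bmpr1a (-3.45), Stag1 (-3.39) and Pecam1 (-1.93). The list medians of nerve and Schwann cell genes (-1.84), blood and vessel genes (-1.69), basal keratinocyte genes (-0.96) and proliferation genes (-0.26) were also lowest on array 2, apart from the other arrays. Array 8 stood far above the others for Eno3 (7.64), Krt35 (4.83), Dsc1 (2.58), Ednrb (2.26) and Lep (1.46). Single values apart from the rest were also those of Cntn1 on array 4 (3.21), Padi3 on array 3 (0.88) and Mcpt2 on array 5 (0.15).

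The keratin-associated protein genes had a median below 0 on all 8 arrays. In a table already turned, a dye bias of these probes would give medians of opposite sign in the 2 orientations, so the pattern itself, with the higher of the 2 means at -0.87, argues against it without being a separate test, and only under that reading of the table. A single array carrying the list is argued against by the highest adjusted p without 1 array, which was 1.5e-04. Signal shared between members by cross-hybridization stays open, since the estimated correlation of 0.057 rested on 3 members with values on all arrays and probe sequences were not analysed here. The genotype is the biological explanation that the design names, and it may account for the shift, as a hypothesis found and tested on the same arrays.

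A part of the ratios followed the dye orientation. If the table held one dye over the other, this part would be the genotype effect, and spots of the same gene would then differ alike on every array. The median correlation over Gapdh spots between arrays of opposite orientation was -0.45, which argues against that reading. A dye bias that differs from spot to spot, in a table already turned, needs a positive correlation between arrays of the same orientation, and the median there was 0.55. No biological explanation was tested for spots of the same gene.

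Lower calls outnumbered higher ones, at 83.9% of called probes, under the reading of the table used here. With the ratios read as Cy5 over Cy3, 16.7% of called probes were lower (533 higher and 107 lower). Read as Cy3 over Cy5 these 2 counts would swap, so a reading by dye does not settle the direction of the excess. Centring each array on its median gave 86.6%, but moved the median fitted ratio of all probes by only -0.02, so it does not decide whether the centring of the arrays plays a part. With arrays 4 to 8 alone, 100 of 103 calls were lower (97.1%), so an excess was present without arrays 1 to 3. The size of that share does not weigh these arrays. With all 8 arrays and a fold of 1.2 the share was also high (95.3% of 214 calls). Array weights gave 527 higher and 1029 lower calls, and quantile normalization 380 and 757, against 81 and 423, so calls of both directions rose and the lower share of these fits decides nothing. Missing values stay open, with 66.4% among probes measured on all 8 arrays, and a real excess of lower transcripts in the mutant may remain beside all of these.

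The arrays can be divided into 4 with the mutant in Cy5 and 4 with the mutant in Cy3 in 35 ways. Only 1 of the 35, the real one, gave as many as 504 probes, with 0 in the highest of the others. For genes 1 of the 35 reached 131, and the highest of the others gave 1. This is the smallest share that 35 splits can give, and each other split turns the ratios of 2 or 4 arrays. Any part common to all arrays then adds to the spread around the fit and lowers the counts of the other splits. The distance between the counts is therefore no measure of strength. Chance can be excluded for both counts only as far as the arrays are exchangeable, which is not known, since they are not separate animals.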

How the results depend on the processing

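The readings of the table by dye, arrays 4 to 8 alone, for the lists scaling and quantile normalization, and for the lists and Hr the looser filter were chosen after seeing the data. The 504 probes became 258 without a dye term, 1137 with quantile normalization, 307 with consecutive arrays averaged, 1556 with array weights, 214 with a fold of 1.2 and 103 with arrays 4 to 8 alone (fewer arrays), and ran from 238 to 502 without 1 array. The 131 genes became 64, 360, 491, 60 and 8 under the same settings apart from averaging, 212 with scaling and 81 with values on all 8 arrays (1613 genes tested). They ran from 53 to 130 without 1 array. With the ratios read as Cy5 over Cy3 there were 66 genes, 62 higher and 4 lower, 2 of them shared in the same direction. The excess of lower calls turned under that reading, also for probes (533 higher and 107 lower). Read as Cy3 over Cy5, higher and lower would swap and the excess of lower calls would be kept. Below, read by dye means Cy5 over Cy3, and every such direction would turn for Cy3 over Cy5. The dye effect fell to 407 probes with centring. The count of lists past the test, 3 of 22, was 1 with averaged arrays, 0 with the ratios read by dye and 1 to 3 without 1 array. With an estimated correlation it was 1 of 16 lists tested. Fry called 5 of 19 lists, 2 of them shared, with inner root sheath (0.0145), epidermal differentiation (0.0243) and proliferation (0.0396) added. The keratin-associated list turned upward when read by dye (adjusted p = 0.413). It kept its call under every other setting of camera that was run and under fry (adjusted p = 0.0145, on 3 members). The exact sign-flip test over arrays did not call it after adjustment over the lists (adjusted p = 0.115). The dermal list also turned when read by dye (0.930), and had adjusted p of 0.119 averaged, 0.679 with an estimated correlation and 0.00758 to 0.134 without 1 array. The ribosomal list had 0.119, 0.679, 0.333 under fry, 0.941 by dye and 0.00324 to 0.212 without 1 array. Hr ran from -0.32 to 0.03 without 1 array, within 1 SD of its mean, and had a single probe. The 24 named genes kept their call in 351 of 483 fits other than the reading by dye. Their direction held in all 483, but the naming rule asked for the same sign on every array. That all but fixed the direction in advance, so it lends no support. Read by dye none of the 24 was past the threshold in its direction, and 8 turned, Krt1 (-0.40), Pramel3 (-0.37), Sfrp1 (-0.33), Vim (-0.71), Igfbp7 (-0.12), Surf6 (-0.27), Pa2g4 (-0.10) and Ilf2 (0.20), as did Krtap9-1 (0.35), Krtap15 (0.50) and Rpsa (0.14). Among genes of the report not past the test, values moved by over 1.5 times without 1 array for Cntn1, which turned (-0.08 to 0.75), Tgm3 (-0.69 to -0.01), Krt35 (0.11 to 0.90), Azin1 (0.08 to 0.27), Lep (0.19 to 0.56), Vdr (-1.18 to -0.47), Pkp3 (-0.38 to -0.14), Padi3 (-0.44 to -0.16), Cyp51 (0.43 to 0.95), Col7a1 (0.38 to 0.92), Vcan (0.49 to 1.02), Atp5b (0.39 to 0.73) and Bmpr1a (-1.18 to -0.62). Apart from smaller numbers of arrays or genes, the cause was not tested. Each pair of consecutive arrays carries opposite dyes, as dye-swap pairs would, but the labels do not say whether they share animals, so the pairing stays open. With these pairs as a random block (correlation 0.187 for probes and 0.189 for genes) there were 352 probes and 88 genes. Without the call there were 8 of the 24 named genes (Npdc1, Sfrp1, Surf6, Pa2g4, Aspn, Has1, Vax1 and Sh3bp5l) and 5 of 11 others (Krtap14, Krt71, Fbn1, Mbp and Rpsa). With the pairs averaged these were 4 of 22 tested (Igfbp7, Surf6, Pa2g4 and Aspn) and 5 of 11 (Krt71, Fgf5, Fbn1, Mbp and Rpsa). Spot signals over background were not analysed here, so what dim spots limit is unknown.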

Other observations

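The families of genes by symbol and the region around Hr were examined after the main results were seen. Among 37 families of at least 8 tested genes with a shared symbol stem, 3 had an adjusted p below 0.05 with the preset correlation. The keratin-associated proteins were 1 of them, with the same 8 genes and the same test as the fixed list, so this adds no support. The small ribosomal subunit family, given below, overlaps the fixed list of cytosolic ribosomal proteins. The late cornified envelope genes, which form part of the outer epidermal barrier, had 8 of 9 members above 0 and a median of 0.56 (adjusted p = 0.0175, and adjusted p = 0.271 with an estimated correlation). The genes of small ribosomal subunit proteins had 19 of 21 above 0 and a median of 0.35 (adjusted p = 0.0390, and adjusted p = 0.877 with an estimated correlation). Both medians stayed above 0 with centring, scaling and quantile normalization of the arrays. These settings moved the median of all genes by only -0.014, -0.025 and -0.002, too little to test the sign.

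Some lower genes outside the rule were picked by hand after their values were seen, so they stand for no tested theme. They were Ovol2 (-1.54), Ehf (-1.50), Hyal2 (-1.32), Socs3 (-1.25) and Gjb5 (-1.21), each past the threshold in limma.

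A regional change around the Hr locus was tested with the 20 nearest measured genes, 10 on each side in the gene order of GRCm38.p6. Their mean absolute z was at percentile 46.5 of 5223 windows of neighbouring genes, and 0 of them passed, the smallest adjusted p being 0.0606. The neighbours did not stand apart from other windows, and the bounds of this test were set before its result was seen.

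Blank spots carried values on few spots, between 10 and 25 of 864 on an array. Their medians were 2.65, 3.72, 1.17 and 0.52 on the arrays with the mutant in Cy3 and -3.33, -1.25, -3.72 and 1.17 on those with the mutant in Cy5 (exact permutation test, two-sided, p = 0.0571). The spots of buffer had medians from -0.51 to 0.42.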
